A study of Mus musculus with 22 samples.

How the data were processed

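RNA of kidneys from wild-type mice and from mice deficient in Clock, the transcription factor that pairs with Arntl to drive the circadian oscillator, was measured on 22 Affymetrix whole-transcript arrays. Per the labels' protocols, the mice were bred from heterozygous pairs, adapted for 2 weeks to 12 hours of light and 12 hours of dark, and kept in constant darkness for 30 hours before sacrifice. Kidneys were taken every 4 h at 6 circadian times, given as zeitgeber time (ZT), where ZT0 is the time of lights on and ZT12 that of lights off in the earlier cycle. Each array held RNA pooled from 2 or 3 mice, of which 100 ng was labelled, so mice within a pool cannot be told apart. The labels name the whole kidney as the source and the left kidney as the tissue. They give 11 arrays per genotype, with 2 pools at each time except 1 pool for the wild type at ZT8 and 1 for the knockout at ZT16. Nothing in the labels says that pools were made from separate litters or on separate days, so p-values measure the spread between these pools.

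The deposited values are log2 expression per probe set, made by the authors with RMA, per the submitters' processing notes. RMA corrects background, brings all arrays to one distribution by quantile normalization and summarises the probes of a set, so a shift of most genes in one direction would be removed, and dim probe sets are compressed toward the floor. The software version, the genome build and scan dates are not given in the sources used here. Array medians lay between 5.88 and 6.01 log2. Correlations over all probe sets were 0.980 to 0.994 between any pair of arrays and 0.987 to 0.993 within a group, and no array was a copy of another. Arrays carry no read depth, and their number limits the precision.

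The table held 35556 probe sets, of which 21789 have 1 gene symbol in the platform annotation, 1621 have several and 12146 are not listed there and stay unnamed. Of the 1-symbol probe sets, 21698 matched the RefSeq gene table of GRCm38.p6 by gene number, and 0 symbols changed. That table was used for names and for which genes neighbour each other. Probe sets below the 30th percentile of the mean over all arrays were left out, and the brightest probe set stood for each gene, which left 13967 genes.

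The main model was fitted with limma 3.58.1 in R 4.3.3 to all 22 arrays, with a mean, a cosine and a sine of a 24 h period for each genotype and 16 residual degrees of freedom. It gave the knockout minus wild-type difference of the means over the cycle, a test of rhythm in each genotype, and a test of the difference between both rhythms. Amplitude is the distance from the fitted mean to the fitted peak in log2. The difference between rhythms is the length of the vector between the fitted waves. Differences at each time came from a limma fit of the 12 group means with 10 residual degrees of freedom, where a group of 1 pool is assumed to vary like the others. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p below are limma's unless another test is named. Errors after ± are standard errors of the fit unless SD or another source is written.

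Before the data were examined, 40 gene lists were fixed, along with the rule for named genes, the tests and the alternatives. The lists cover the circadian clock and its outputs, transport of sodium, water, other ions, acid and organic ions, blood pressure systems, metabolism, stress responses, cell types of the kidney and of neighbouring tissue, and sex. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 40 lists, and list members called for rhythm were counted against all genes with Fisher's exact test, two-sided. The named genes were Clock, the 12 largest rises and 12 largest falls with the same sign at all 6 times, the 20 largest amplitudes in wild type, the 10 largest in knockout, the 12 largest rhythm differences, 2 genes per direction at each time, and up to 4 members per list, with any member of the clock, sodium, water, renin-angiotensin and 20-HETE lists. Genes within 10 Mb of Clock were compared with all others by Fisher's exact test, two-sided.

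The models were tested on simulated data with 200 changed genes among 13967. At a log2 size of 0.5, 98.5% of changed means, 96% of rhythms in either genotype, 84.5% of rhythm differences and 47% of differences at a single time were recovered. At 0.25, the shares were 71% for means, 67% for wild-type rhythm, 58.5% for knockout rhythm, 16% for rhythm differences and 0% for a single time. The simulated noise was independent between genes and between arrays. Residuals of the real arrays were not, as described below, so these shares hold for a cleaner setting than the data. The alternatives were other filters, every probe set on its own, array medians subtracted, a repeated quantile normalization, the pool number as a block, group means in place of waves, a trended robust spread, array weights, a minimum size, 1 genotype at a time, other windows, and leaving out each array. Fits without doubted arrays and within each pool number were added after seeing the data.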

Results

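The data are log2 expression values of 13967 genes in mouse kidney, from 11 wild-type (WT) and 11 Clock knockout (KO) arrays spread over 6 circadian times. Each array is a pool of 2 or 3 mice. The study's title sets the work in the context of renal excretory rhythms, and the design asks which kidney transcripts depend on Clock and on the time of day.

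Clock itself was measured first. Its probe set averaged 8.86 ± 0.24 (SD, n = 11) in WT and 8.95 ± 0.11 (SD, n = 11) in KO. Single WT arrays read 9.16 and 9.10 at ZT0, 8.81 and 8.91 at ZT4, 8.49 at ZT8, 8.63 and 8.47 at ZT12, 8.87 and 8.93 at ZT16, and 9.06 and 9.01 at ZT20. Single KO arrays read 9.02 and 9.00 at ZT0, 8.85 and 8.97 at ZT4, 8.98 and 8.73 at ZT8, 8.90 and 8.89 at ZT12, 9.10 at ZT16, and 8.96 and 9.11 at ZT20. The KO minus WT difference was 0.13 ± 0.04 log2 (adjusted p = 0.0398), a call lost in 12 of the 22 fits that leave out 1 array. The adjusted p was 0.0683 without the KO ZT20 pools, 0.252 within pool 1 and 0.608 within pool 2. The difference stayed near its size there, at 0.140, 0.128 and 0.118 log2. The probe set sums probes along the transcript, the labels do not name the deleted part, and a signal from outside a deletion remains, so this value does not check the genotype labels.

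Clock genes differed in level between genotypes in both directions. Arntl, the partner of Clock, was higher in KO by 1.01 ± 0.10 log2 (adjusted p = 2.38e-06), as were the repressor Cry1 by 0.69 ± 0.08 (adjusted p = 9.72e-06) and Nfil3, a repressor of D-box promoters, by 0.55 ± 0.09 (adjusted p = 0.000619). Lower members were Ciart by -1.08 ± 0.25, Dbp by -0.86 ± 0.22, Nr1d2 by -0.67 ± 0.10, Nr1d1 by -0.55 ± 0.12, Per3 by -0.52 ± 0.09 and Tef by -0.41 ± 0.08, with adjusted p from 0.000157 to 0.0158. A second, slightly dimmer probe set of Ciart differed by -0.715 and was not called when every probe set was tested (adjusted p = 0.0717). Per1 (-0.08 ± 0.09), Per2 (-0.11 ± 0.07), Bhlhe41 (-0.26 ± 0.13) and Cry2 (0.18 ± 0.06) did not pass the test. Of the 10 core repressors measured, 1 was higher, 4 were lower and 5 were not called, over all genes and, adjusted over the list alone, 2 and 4. Their shift as a list had an adjusted p of 0.047 in camera, and adjusted p = 0.433 with an estimated correlation, and that call was lost in 11 of the 22 fits that leave out 1 array. Of 4 core activators, 2 were higher and 1, Rora (-0.18 ± 0.05), was lower. Among the 12 measured clock output genes, 4 were lower, including Tspan4 (-0.41 ± 0.05), Gys2 (-0.39 ± 0.08), Alas1 (-0.28 ± 0.06) and Usp2 (-0.28 ± 0.07), and Dtx4 was higher (0.39 ± 0.07).

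**Figure D1:**
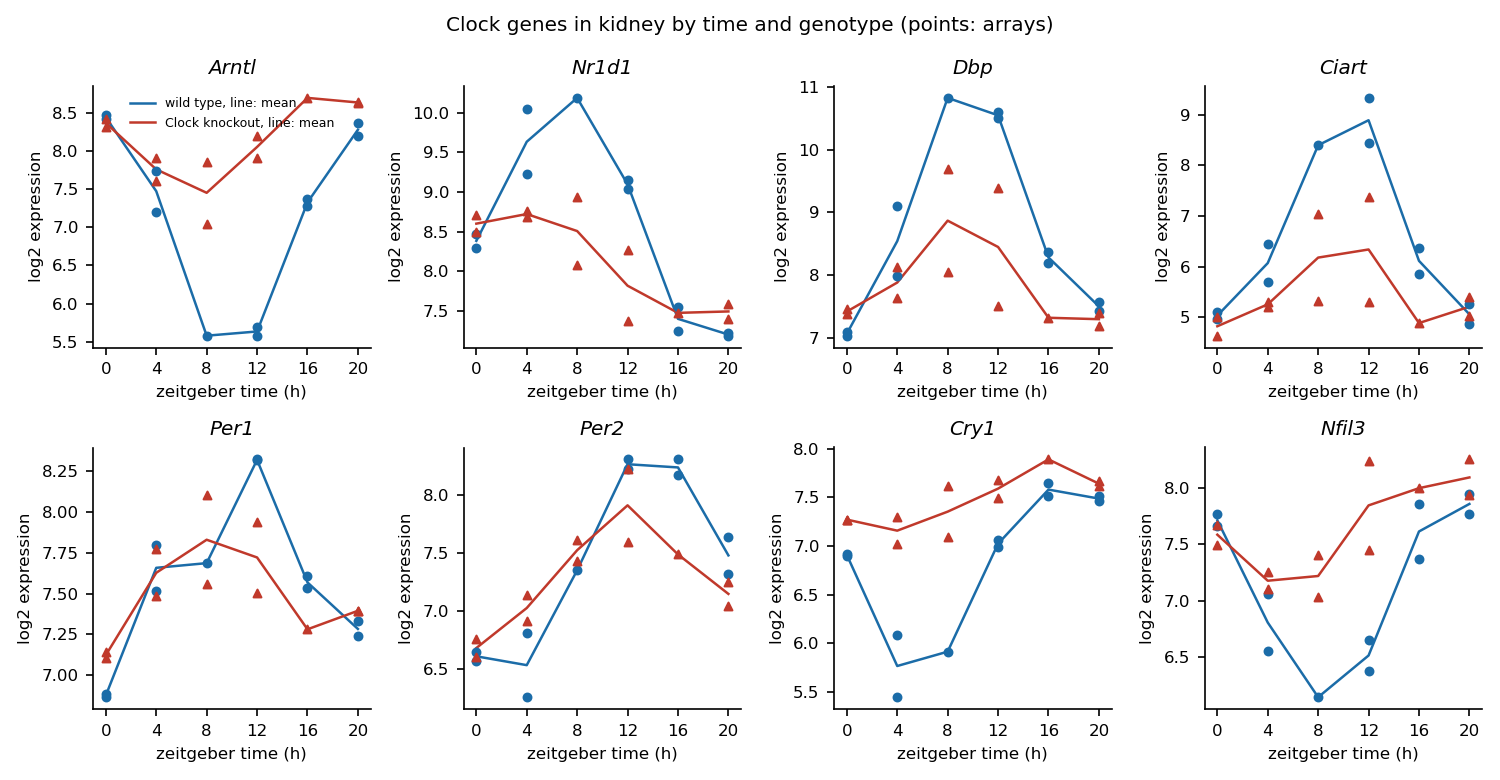
Log2 expression of 8 clock genes against zeitgeber time (h), with a point per array (circles, wild type; triangles, knockout) and lines through the group means. Arntl and Cry1 lie higher in knockout at ZT8, by 1.87 and 1.44 log2, and the wild-type waves of Dbp and Ciart have fitted amplitudes of 1.91 and 2.07.

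Over the whole cycle, 1276 genes differed between genotypes, 731 higher and 545 lower in KO. Among called genes with the same sign at all 6 times, the largest rises were in the amino acid transporter Slc7a12 (2.38 ± 0.30 log2, adjusted p = 2.71e-05), the fibrinogen chains Fgg (1.40 ± 0.19) and Fgb (0.90 ± 0.11), Atp10d (1.19 ± 0.11), Ugt2a3 (1.06 ± 0.23), the peroxisomal oxidase Hao2 (1.05 ± 0.08), the drug efflux pump Abcb1b (1.04 ± 0.09), the mitochondrial arginase Arg2 (1.02 ± 0.11), Pla2g7 (0.93 ± 0.09), Fabp7 (0.89 ± 0.11), Slc22a29 (0.89 ± 0.14) and Kynu (0.82 ± 0.15). The largest falls among them were in Ugt2b38 (-3.68 ± 0.32, adjusted p = 6.49e-07), Nat8f5 (-2.55 ± 0.22), Cyp4a12a (-1.93 ± 0.33), Cyp4a12b (-1.67 ± 0.25), the organic anion transporter Slco1a1 (-1.63 ± 0.35), Ugt2b5 (-1.36 ± 0.15), Ugt2b37 (-1.31 ± 0.22), Pzp (-1.30 ± 0.24), Cyp7b1 (-1.20 ± 0.27), Gm15441 (-1.01 ± 0.18), Alb (-0.97 ± 0.13) and Ces1d (-0.92 ± 0.09). Outside that limit, Cyp4a14 (1.32), Arntl (1.01), Slc22a26 (-1.18) and Ciart (-1.08) changed by as much as some of these. Ugt2b, Cyp4a and Nat8 genes have close paralogs, and probes may read more than one of them. Atp10d, Ugt2a3, Ugt2b38, Ugt2b5, Ugt2b37 and Alb lie within 20 Mb of Clock on chromosome 5. For them, an effect of sequence that travels with the targeted locus, taken up below, cannot be told apart from one of Clock. Most differences were small, with 44 higher and 51 lower genes at 0.5 log2 or more. Subtracting array medians turned the split into 1111 higher and 343 lower, so the balance of directions rests on the normalization.

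The pool number acted as a possible batch. A component with 14.1% of the residual variance had 11 of the 12 pool 1 arrays above 0 and all 10 pool 2 arrays below 0. Within pool 1, 565 genes were called, and 548 of them had the same sign in the pool 2 arrays, against 9774 of all 13967 genes. Pool 2 arrays alone gave 1 called gene. The 10 pool 2 arrays include all 3 that lay between the genotypes (KO ZT8, KO ZT12 and WT ZT4), described below. Smaller differences within pool 2 can therefore not be laid to a batch alone. Arntl differed by 1.18 log2 within pool 1 and 0.77 within pool 2, Ugt2b38 by -4.30 and -2.85, Slc7a12 by 2.63 and 1.95, and Dbp by -1.34 and -0.15.

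**Figure D2:**
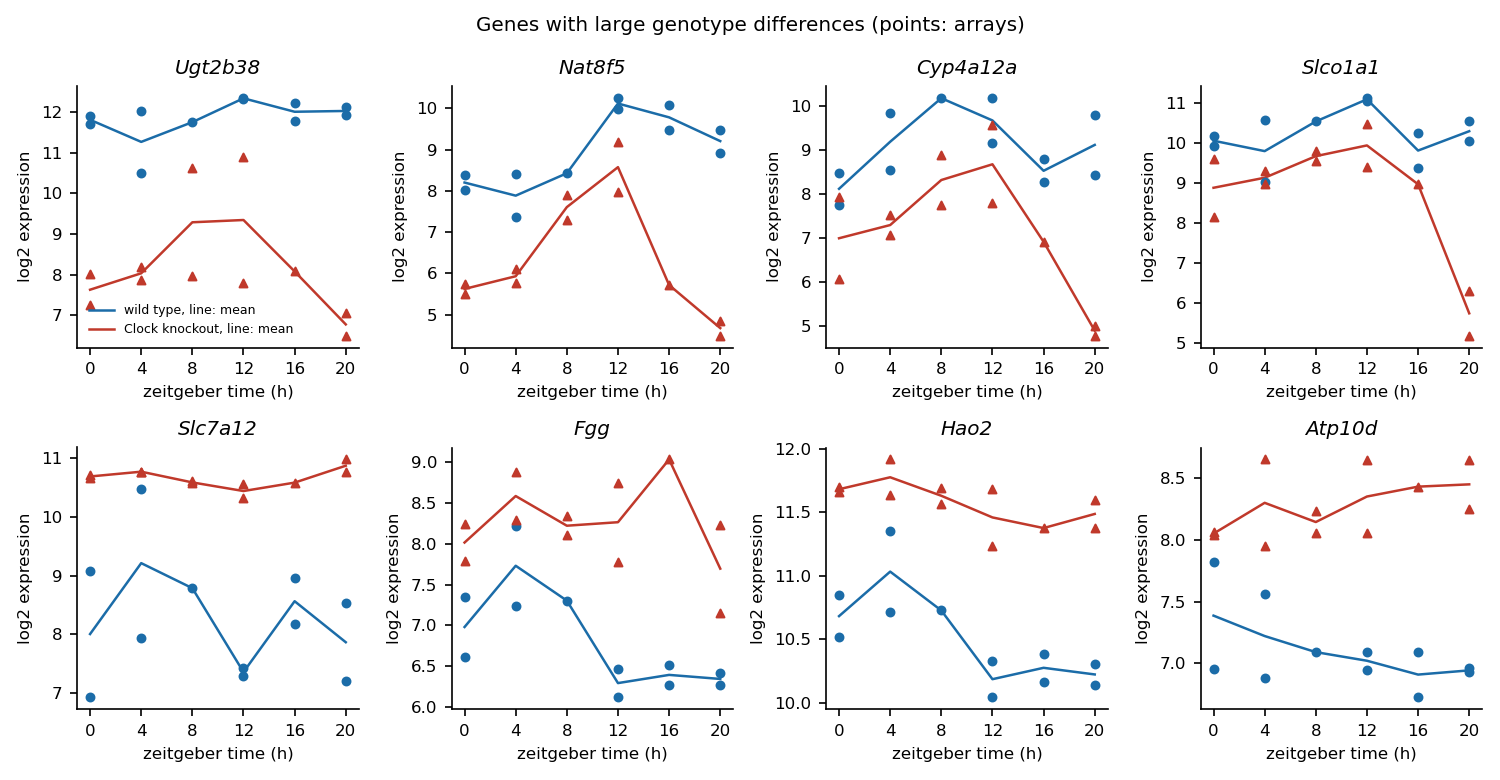
Log2 expression of 8 genes with large genotype differences against zeitgeber time (h), with a point per array (circles, wild type; triangles, knockout) and lines through the group means. Ugt2b38 is lower in knockout by 3.68 log2 over the cycle (difference -3.68) and Slc7a12 higher by 2.38, and the lowest Cyp4a12a values, 5.02 and 4.79, are those of the knockout pools at ZT20. Ugt2b38 and Atp10d lie within 20 Mb of Clock on chromosome 5.

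Genes that differ between male and female mouse kidney formed the list with the most falls. Of 14 measured members, 11 were lower in KO, 2 were higher and 1 was not called, with a median of -0.52 log2 (camera adjusted p = 2.09e-06, and adjusted p = 0.144 with an estimated correlation). Besides Cyp4a12a and Slco1a1, Acsm3 (-0.66 ± 0.09) was lower, and Cyp4a14, an omega-hydroxylase, was higher (1.32 ± 0.25). Of 3 measured sex chromosome genes, 0 were called in limma, and 1 had an unadjusted p under 0.05. The KO pools at ZT20 stood apart here, with Slco1a1 at 6.30 and 5.18 against 8.15 to 10.5 on the other KO arrays. In the largest component of the residuals around the fitted waves (27.8% of their variance, both genotypes), the list members Cyp4a12a, Slco1a1, Cyp7b1 and Cyp2j13 and, outside the list, Azgp1 and Pzp were among the 25 genes at one end, and Top2a, Mki67, Col3a1, Postn and Fn1 among those at the other. Without these KO pools, 639 genes were called, 613 of them shared with the 1276, and Slco1a1 differed by -1.01 log2 (adjusted p = 0.0269) and Cyp7b1 by -0.75 (adjusted p = 0.0452). Of the 111 called members of all gene lists, 76 were called in that fit. The sign was the same in both fits for 111, which is nearly forced, since the fits share most arrays. Among those that lost the call are Rora, Calb1, Slc16a7, Slc14a2, Nfat5, Aqp11, Slc9a2 and Agtr1a, with adjusted p from 0.0678 to 0.214. Their differences changed little for Rora (-0.177 to -0.167), Calb1 (0.245 to 0.218), Slc16a7 (0.189 to 0.165), Aqp11 (-0.152 to -0.137) and Agtr1a (0.129 to 0.135). They shrank more for Slc14a2 (0.184 to 0.143), Nfat5 (0.177 to 0.139) and Slc9a2 (-0.224 to -0.167).

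The lists of distal convoluted tubule markers and of acid-base genes, the latter from several nephron segments, shifted upward in KO. Of 7 distal convoluted tubule markers, 5 were higher and 0 lower, led by the magnesium channel Trpm6 (0.37 ± 0.05), Pvalb (0.31 ± 0.06), Calb1 (0.24 ± 0.06) and Slc16a7 (0.19 ± 0.05), with a camera adjusted p of 6.29e-06, and adjusted p = 0.0478 with an estimated correlation. Of 15 acid-base genes, 8 were higher and 0 lower, including the glutamine transporter Slc38a3 (0.46 ± 0.05), Atp4a (0.28 ± 0.07), the ammonia transporter Rhbg (0.22 ± 0.03) and the anion exchanger Slc4a1 (0.21 ± 0.04), with camera adjusted p of 6.29e-06, and 0.0478 with an estimated correlation. Of 15 potassium, calcium, magnesium and phosphate genes, 6 were higher, among them Slc8a1 (0.37 ± 0.06) and Trpv5 (0.31 ± 0.05), and the potassium channel Kcnma1 (-0.23 ± 0.05) was lower. That list had a camera adjusted p of 0.000184, and adjusted p = 0.219 with an estimated correlation. Principal cell markers had 3 of 9 members higher (adjusted p = 0.047) and intercalated cell markers 4 of 10 (adjusted p = 0.0112), and with an estimated correlation their adjusted p were 0.415 and 0.326. The principal cell call was lost in 11 of the 22 fits that leave out 1 array. Other cell types moved too, with endothelial markers upward (camera adjusted p = 0.0104) and proximal tubule markers 4 lower and 2 higher of 15 (camera adjusted p = 0.0716). With an estimated correlation, these were 0.395 and 0.433, each an adjusted p. Shares of cell types were not measured, so these shifts are not separated from a change in tissue make-up.

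Genes of salt and water balance changed in both directions, and camera asks only for a shared one. A mixed test of change in either direction (limma's fry), not planned, gave adjusted p of 1.37e-08 for water and urea genes. It gave 0.00042 for sodium transport, 1.76e-05 for its distal regulators and 1.37e-08 for 20-HETE enzymes. That test asks whether any members change, not whether more do than among all genes. Among 15 water and urea genes, the vasopressin receptors Avpr1a (0.75 ± 0.07, adjusted p = 6.49e-07) and Avpr2 (0.28 ± 0.06) and the urea transporter Slc14a2 (0.18 ± 0.04) were higher, as was Nfat5 (0.18 ± 0.05), and Aqp11 (-0.15 ± 0.04) was lower. That list did not pass in camera (adjusted p = 0.0606). Among 12 sodium transport genes, the epithelial sodium channel subunit Scnn1g (0.20 ± 0.04) was higher and the exchanger Slc9a2 (-0.22 ± 0.06) lower (list adjusted p = 0.124). Of 14 regulators of distal sodium transport, Klhl3 (0.18 ± 0.03) was higher and Usp2 lower (list adjusted p = 0.253). In the renin-angiotensin list, Agt (0.35 ± 0.06), Mme (0.28 ± 0.04) and Agtr1a (0.13 ± 0.04) were higher among 6 members (camera adjusted p = 0.0116, and adjusted p = 0.162 with an estimated correlation). Of 15 enzymes of 20-HETE and eicosanoid synthesis, Cyp4a14 and the epoxygenase Cyp2c23 (0.72 ± 0.08) were higher, and Cyp4a12a, Cyp4a12b, Cyp2j13 (-0.84 ± 0.19) and the epoxide hydrolase Ephx2 (-0.39 ± 0.05) were lower (list adjusted p = 0.404). Without the KO pools at ZT20, Cyp2j13 differed by -0.47 and lost its call (adjusted p = 0.0504).

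Amino acid metabolism was the metabolic list that shifted. Of 16 members, 9 were higher and 2 lower (camera adjusted p = 0.000104, and adjusted p = 0.0478 with an estimated correlation), with Slc7a12, Arg2, Hpd (0.55 ± 0.07) and Agxt2 (0.42 ± 0.04) leading. Fatty acid oxidation had 2 higher and 5 lower of 17, including Angptl4 (-0.56 ± 0.09), glucose handling 3 higher of 14, cholesterol synthesis 3 lower of 14, organic ion transport 2 higher and 5 lower of 16, and NAD and redox genes 1 higher and 2 lower of 15, and the camera adjusted p of these lists ran from 0.12 to 0.184. Endothelial markers had 3 of 9 higher, among them Plvap (0.33 ± 0.04), immune cell markers 2 of 15 lower and interferon genes 2 of 9 higher, with camera adjusted p of 0.0104, 0.0139 and 0.0124. With an estimated correlation, these were 0.395, 0.433 and 0.433, each an adjusted p, and the immune cell call was lost without WT pool 2 at ZT4 (adjusted p = 0.0796). Proliferation and stromal lists had 0 members called in limma among 13 and 11, and 0 at an unadjusted p under 0.05.

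In WT, 905 genes were rhythmic. The largest amplitudes were those of Ciart (2.07 ± 0.25 log2, peak at ZT10.2), Dbp (1.91 ± 0.22, ZT9.95), Arntl (1.55 ± 0.10, ZT22.2), Nr1d1 (1.54 ± 0.12, ZT6.90), Nat8f5 (1.12 ± 0.22, ZT14.7), Nr1d2 (1.08 ± 0.10, ZT9.64), Per2 (0.97 ± 0.07, ZT14.2), Cry1 (0.97 ± 0.08, ZT17.7), the monocarboxylate transporter Slc16a1 (0.93 ± 0.09, ZT23.1) and Nfil3 (0.90 ± 0.09, ZT20.5). Fabp7, Per3, Upp2, Zbtb16, Angptl7, Rhobtb1, Tc2n, Fgg, Avpr1a and Bhlhe41 followed, with amplitudes from 0.79 to 0.69. The Fgg call (adjusted p = 0.0479) was lost in 16 of the 22 fits that leave out 1 array, and those of the other 19 genes in 0. All 10 core repressors and all 4 genes of the PAR bZIP and Nfil3 list were called (Fisher's exact test, adjusted p = 4.98e-11 and 0.00014), as were 9 of 12 clock output genes. Heat shock genes had 7 of 13 members rhythmic (adjusted p = 5.69e-05), with Hspa5 (0.55, ZT18.9) and Hsph1 (0.41, ZT17.6) peaking in the subjective night. Glucocorticoid-responsive genes had 8 of 14 (adjusted p = 8.50e-06), including Zbtb16 (0.77, ZT13.3) and Tsc22d3 (0.64, ZT14.9). Sgk1 (0.43, ZT17.5), the sodium-proton exchanger Slc9a3 (0.25, ZT7.5) and the cold-inducible Cirbp (0.54, ZT7.0) and Rbm3 (0.34, ZT10.3) were also rhythmic. Peaks gathered around ZT8, with 360 genes, against 59 around ZT16. Fits with a free level at each time called 140 genes, and the 11 WT arrays alone called 363.

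In KO, 343 genes were rhythmic, and 158 of them were also rhythmic in WT, where independent lists would share 22.2. Both tests use the same estimate of the spread of each gene, so the lists are not independent and 22.2 may be too low. The clock genes called in both included Arntl (KO amplitude 0.62 ± 0.10), Nr1d1 (0.74 ± 0.12), Nr1d2 (0.74 ± 0.10), Per2 (0.56 ± 0.07), Per3 (0.52 ± 0.09) and Nfil3 (0.52 ± 0.09). Dbp (0.78 ± 0.22, adjusted p = 0.109), Ciart (0.72 ± 0.25, adjusted p = 0.256) and Cry1 (0.33 ± 0.08, adjusted p = 0.076) did not pass in KO. The largest KO amplitudes were those of Nat8f5 (1.70 ± 0.22), Azgp1 (1.65 ± 0.30), Slco1a1 (1.60 ± 0.35), Cyp4a12a (1.54 ± 0.33), Pzp (1.26 ± 0.24), Ces1g (1.15 ± 0.23), Ugt2b37 (1.15 ± 0.22), Cyp7b1 (1.14 ± 0.27), Cyp4a12b (1.10 ± 0.25) and Cyp2j13 (1.06 ± 0.19). Of the 22 fits that leave out 1 array, 19 lost the call of Cyp7b1, 10 that of Cyp4a12b, 5 that of Cyp4a12a, 4 that of Slco1a1, 3 that of Ces1g, 2 each those of Azgp1, Pzp, Ugt2b37 and Cyp2j13, and 0 that of Nat8f5. Of the sex-dimorphic list, 7 of 14 members were rhythmic in KO and 0 in WT. Without the KO pools at ZT20, 12 genes were rhythmic in KO, and leaving out pool 2 at ZT20 alone left 77. In that fit without both pools, the KO amplitude was 0.56 for Slco1a1, 0.46 for Cyp7b1, 0.40 for Cyp2j13, 0.95 for Cyp4a12a and 1.51 for Nat8f5 (adjusted p = 0.0386). It was 0.71 for Arntl (adjusted p = 0.111), 0.71 for Nr1d2 (adjusted p = 0.111), 0.50 for Nfil3 (adjusted p = 0.223) and 0.59 for Per2 (adjusted p = 0.00757). Without the ZT20 pools of both genotypes, 510 genes were rhythmic in WT and 8 in KO.

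**Figure D3:**
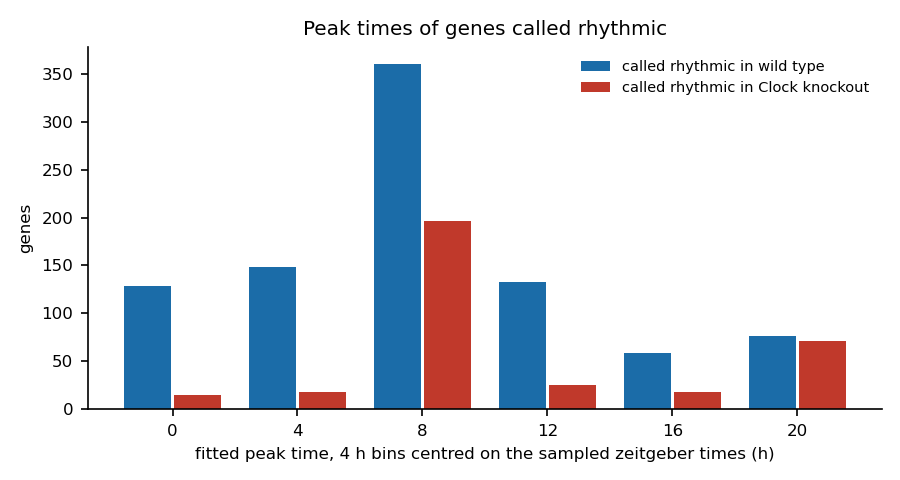
Number of genes (vertical axis) by fitted peak time in 4 h bins centred on the sampled zeitgeber times (horizontal axis, h), for genes called rhythmic in wild type (left bars) and in knockout (right bars). The bin at ZT8 is the tallest in both, with 360 and 196 genes.

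In the 158 genes rhythmic in both genotypes, KO peaks came earlier. The median shift was -2.17 h with quartiles of -2.98 and -1.16 h, and 149 genes peaked earlier against 9 later. Without the KO pools at ZT20, 11 of these genes were called in both genotypes, with a median shift of -2.34 h, and over the same 158 genes the median was -2.15 h, with 148 earlier and 10 later. Arntl peaked at ZT22.2 in WT and ZT19.0 in KO, and Per2 at ZT14.2 and ZT12.3. The median ratio of KO to WT amplitude was 0.914 in these genes, 0.546 over the genes called in WT and 1.36 over those called in KO. The last pair is pulled apart by choosing genes on one side of the ratio.

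The rhythms differed between genotypes in 6 genes, with 1087 at an unadjusted p under 0.05. They were Arntl (difference 1.24 ± 0.14 log2, adjusted p = 0.00124), Ppard, a fatty acid receptor (0.53 ± 0.07, adjusted p = 0.0141), Ddc, which makes renal dopamine (0.52 ± 0.08, adjusted p = 0.0227), Rhobtb1 (0.57 ± 0.09, adjusted p = 0.027), Ypel2 (0.57 ± 0.09, adjusted p = 0.027) and Nr1d1 (1.06 ± 0.17, adjusted p = 0.0316). Ppard kept most of its amplitude, 0.66 in WT and 0.53 in KO, and its peak stood at ZT22.7 and ZT19.3. For the other rhythms called in 1 genotype, the difference did not pass this test. Without 3 pools that lay between the genotypes, a choice made after seeing the data and one that favours a difference, 20 genes passed, among them Dbp (1.70, adjusted p = 0.000105) and Ciart (1.94, adjusted p = 0.0015). Of the 22 arrays left out in turn, 9 took the count to 3 or fewer, with 1 gene without WT pool 2 or KO pool 1 at ZT0. Arntl kept its call in all 22 fits, and the call was lost in 3 for Ppard, 6 for Ddc, 9 for Ypel2, 12 for Rhobtb1 and 16 for Nr1d1.

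At single times, with 1 or 2 pools per group, 4 genes differed at ZT0, 1 at ZT4, 4 at ZT8, 17 at ZT12, 2 at ZT16 and 244 at ZT20. At ZT0, the sex-dimorphic transporter Abcc3 (0.88 ± 0.13) and Slc23a3 (0.80 ± 0.12) were higher and Nat8f5 (-2.58 ± 0.38) lower. Cry1 was higher at ZT4 (1.39 ± 0.18) and at ZT8, where Arntl was higher too. At ZT12, Arntl (2.42 ± 0.21) and Slc16a1 (1.41 ± 0.18) were higher and Tmem237 (-0.63 ± 0.10) lower. At ZT16, Ddc was higher (1.22 ± 0.14) and Nat8f5 lower (-4.07 ± 0.47). At ZT20, 99 genes were higher, with Slc7a12 (3.01 ± 0.68) and Slc22a29 (1.65 ± 0.31) leading, and 145 lower, with Ugt2b38 (-5.26 ± 0.83) and Slco1a1 (-4.55 ± 0.53) leading. Of the fits that leave out 1 array, 16 lost the ZT0 call of Abcc3, 18 that of Slc23a3 and 16 that of Nat8f5. The Cry1 call was lost in 2 at ZT4 and 17 at ZT8, and the Arntl call in 11 at ZT8 and 0 at ZT12. With the pool number as a block or with array weights, no gene passed at ZT4, so the Cry1 call there was lost. Losses were 2 for Slc16a1 and 3 for Tmem237 at ZT12, 0 for Ddc and Nat8f5 at ZT16, and at ZT20 11 for Slc7a12, 2 for Slc22a29, 2 for Ugt2b38 and 0 for Slco1a1. The count at ZT20 was 21 without WT pool 2, 68 without KO pool 1 and 46 without KO pool 2 of that time.

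Genes near Clock were called more often. Within 10 Mb of Clock on chromosome 5, by gene order in GRCm38.p6, 12 of 55 genes differed between genotypes (21.8%), against 1260 of 13875 elsewhere (9.08%), an odds ratio of 2.79 (95% interval 1.34 to 5.41; Fisher's exact test, two-sided, p = 0.00346). Atp10d (1.19) and Stap1 (0.42) had the largest rises and Shisa3 (-0.37) and Fryl (-0.25) the largest falls there. Of 503 other windows of the genome, 3 had as high a share, and 60 had as high a mean of their 5 largest absolute differences (0.487 log2 near Clock, up to 1.23 elsewhere). The windows span 20 Mb and start every 5 Mb, so neighbours overlap and the 503 are not independent. On chromosome 5, the window starting at 90 Mb had 21.78% called, just short of the 21.82% near Clock. Windows overlapping the one around Clock were left out of the 503. Among those left out on chromosome 5, the window starting at 65 Mb had a mean of 0.446 (17.2% called). The window starting at 70 Mb had 1.72 (23.3% called). Ugt2b38, Ugt2b5 and Ugt2b37 lie 10.9 to 11.2 Mb from Clock, just past the cut at 10 Mb. The mean near Clock thus depends on where the window ends. Without WT pool 1 at ZT12, the odds ratio was 1.77, past the threshold no longer. The excess also did not pass without the 3 pools between the genotypes or within pool 1, as given below.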

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

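The tests of low male-typical genes, of arrays between the genotypes, of the surroundings of Clock and of splits with the genotype means removed were chosen after the results were seen, and the other splits of the arrays were planned.

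The waves of 6 genes differed between genotypes in a test of the difference itself: Arntl by 1.24 log2, Nr1d1 by 1.06, Ypel2 and Rhobtb1 by 0.57 each, Ppard by 0.53 and Ddc by 0.52. Of 100 splits of the 22 arrays into groups of 11, the real one included, 2 gave 6 genes or more, fewer than the planned limit. The highest of the others gave 7, more than the real one. The splits mix genotypes, so the mean difference adds to their residual spread and can hold their counts down. With the genotype means removed first, 2 of the same 100 splits again gave 6 or more, the real one and a split with 58. What sets that split apart was not tested. Leaving out 1 array took the real count as low as 1, so chance is not excluded for this count. For the 1276 genes of the mean difference, 1 of 100 splits, the real one, gave as many, and the highest of the others gave 81. A split by pool number, of 12 against 10 arrays, gave 226 genes.

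Probe sets without a single gene symbol were outside the comparisons. Of 13767 such probe sets, 6479 were bright enough to test, and 75 differed between genotypes, 43 higher and 32 lower in KO. They carry several symbols or none in the annotation, so no gene is named.

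Genes higher in male kidney were lowest in the KO pools of ZT20, with Cyp4a12a at 5.02 and 4.79 against 6.07 to 9.56 on the other KO arrays. Female mice in the pools are argued against by 3 Y-linked genes, whose mean was -0.0559 ± 0.0833 log2 relative to the other KO arrays. That error is taken from the SD of the other KO arrays. A smaller share of proximal tubule is argued against by 12 of its markers outside the sex list, with a median of -0.0418 ± 0.0773 log2 at ZT20. This error comes from resampling the 12 markers and leaves out the spread between pools. Less mature animals stay open: the proliferation list fell as the sex-dimorphic list rose over the 11 WT arrays with Pearson r = -0.542 (permutation p = 0.0828; rho = -0.445, permutation p = 0.172; r = -0.459 without the 2 farthest arrays), and over the 11 KO arrays with r = -0.822 (permutation p = 0.0125, adjusted over both relations 0.0249; rho = -0.682, permutation p = 0.0258; r = -0.833 without 2). In KO the 2 left out were the ZT20 pools, after which KO ZT0 pool 1 stood alone, at 9.87 for the sex-dimorphic and 7.14 for the proliferation mean. The other KO arrays lay at 10.30 to 10.73 and 6.24 to 6.41, so the relation was not shown among them. An effect of the hour in KO stays open too, since no other day was sampled, but KO ZT0 pool 1 had the next lowest sex-dimorphic mean (9.87), with a proliferation mean of 7.14 against 7.45 and 6.47 in KO ZT20 pools 2 and 1 and 6.91 in WT ZT20 pool 1, and Col3a1 read 9.33 there and 9.39 and 9.04 in those KO ZT20 pools, against 8.03 to 8.62 on the other KO arrays.

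KO pool 2 at ZT8 and KO pool 2 at ZT12 lay between the genotypes, with Dbp at 9.69 and 9.39 and Ugt2b38 at 10.6 and 10.9, against 6.50 to 8.20 for Ugt2b38 on the other KO arrays. WT mice mixed into these pools may account for this, and would move the genes that travel with the locus as well. WT pool 2 at ZT4 lay between as well, with Slc7a12 at 10.49 (6.93 to 9.08 on the other WT arrays) and Ugt2b38 at 10.51 (11.71 to 12.36), and the test below does not cover it. Over 16 genes within 20 Mb of Clock, chosen without these arrays, the median fraction of the way to WT was 0.25 ± 0.12 at ZT8 and 0.50 ± 0.16 at ZT12. Both errors come from resampling the genes and leave out the spread between arrays. The highest fraction on another KO array was 0.228. Over 599 genes elsewhere, the fractions at ZT8 and ZT12 were 0.440 and 0.679. The spread of these fractions keeps the explanation open. Slc7a12, higher in KO, read 10.61 and 10.32 in these KO pools, against 10.56 to 10.98 on the other KO arrays. RNA of a pool adds up before the log2 is taken, so a minority of WT mice would lower such a gene little. Slc7a12, a single gene with a different reading in each pool, thus does not decide. A difference in physiology between mice of 1 genotype was not tested.

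The excess of called genes near Clock may come from sequence of another strain that travels with a targeted locus, which would reach beyond the window tested. Between 10 and 20 Mb from Clock, 14 of 71 genes were called (19.7%), an odds ratio of 2.48 (95% interval 1.27 to 4.51; Fisher's exact test, two-sided, p = 0.00536). Those 14 include 5 paralogs of 1 cluster (Ugt2b38, Ugt2b5, Ugt2b37, Ugt2b34 and Ugt2a3) and the related genes Alb and Afm, and with each of these 2 families counted once, 9 of 66 were called (13.6%), an odds ratio of 1.59 (95% interval 0.691 to 3.25; Fisher's exact test, two-sided, p = 0.194). The second interval holds both 1 and the odds ratio of 2.79 seen within 10 Mb. The 2 families were picked after their members were seen to be called, and families elsewhere were not merged. Counting them once could thus only lower the share, so the second count is no test of the explanation. The first count went with the explanation, but it takes neighbouring paralogs as separate genes. High shares on chromosome 5 also ran past 20 Mb. In the 20 Mb windows starting at 95 and 100 Mb, 21.1% of 133 and 19.4% of 160 genes were called. These windows hold neither of the 2 families. The share was 13.7% from 105 Mb and 8.11% from 115 Mb. Other parts of the genome reached 25%, and these windows were not tested, so they do not decide. The explanation stays open, and no other allele of Clock was measured.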

How the results depend on the processing

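Fits without doubted arrays and within a pool number were chosen after seeing the data, the others before. Settings not named for a result kept its count within 1.5 times, and the cause of a change was not tested except where fewer arrays or a size limit make it. Called genes for the mean difference (1276; 731 higher, 545 lower) numbered 823 with group means (458 higher), 2351 with array weights (1341 and 1010), 95 at 0.5 log2 or more (44 and 51), 639 without the KO ZT20 pools (374 and 265), 434 without all ZT20 pools (270 and 164), 565 in pool 1 arrays (293 and 272) and 1 in pool 2 arrays (0 and 1), and with medians subtracted 1111 higher and 343 lower. Rhythm in WT (905) fell to 140 with group means, 347 with a minimum size, 363 in WT arrays alone, 510 without all ZT20 pools, 595 without 3 pools between the genotypes (KO ZT8 pool 2, KO ZT12 pool 2, WT ZT4 pool 2), 95 in pool 1 and 14 in pool 2. Rhythm in KO (343) was 228 with no filter, 59 with group means, 697 with array weights, 190 with a minimum size, 195 in KO arrays alone, 12 without the KO ZT20 pools, 8 without all ZT20 pools, 58 without the 3 pools, and 0 in either pool number. Rhythm differences (6) were 10 with the 50th percentile filter, 1 with group means, 11 with array weights, 3 without the KO ZT20 pools, 2 without all ZT20 pools, 20 without the 3 pools, 3 in pool 1 and 0 in pool 2. The 3 pools were chosen because they lay between the genotypes, so a rise without them follows in part from the choice.

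At ZT0 (4 genes), counts were 0 with no filter, 1 with medians subtracted, 2 with a repeated quantile step, 1 with the block, 2 without the KO ZT20 pools and 7 without all ZT20 pools. At ZT4 (1), they were 0 with the block, array weights or no ZT20 pools and 11 without the 3 pools. At ZT8 (4), they were 0 with no filter or without either set of ZT20 pools, 2 with all probe sets and 17 without the 3 pools. At ZT12 (17), they were 39 with the 50th percentile filter or a trended spread, 27 with medians subtracted, 32 with the quantile step and 76 without the 3 pools. At ZT16 (2), they were 4 with the 50th percentile filter, medians subtracted or no KO ZT20 pools, 12 with a trended spread and 28 without the 3 pools. At ZT20 (244), the count was 154 with no filter. Lists called fell from 12 to 3 with an estimated correlation. The odds ratio near Clock (2.79) was 1.95 without the 3 pools (Fisher's exact test, p = 0.0695), 2.38 in pool 1 (p = 0.0714), and 0 in pool 2, where 1 gene was called in all, against p from 6.46e-05 to 0.0462 under the other settings that keep every array or leave out the ZT20 pools.

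The pool numbers were not taken to pair the samples, since the labels name no shared animal, day or batch and deviations of same-numbered pools correlated above 0.1 in 25 of 45 pairs of groups (-0.411 to 0.547; at the same time 0.361, 0.394, 0.00355 and 0.181 for ZT0, ZT4, ZT12 and ZT20). A batch shared by part of the arrays stays open, with 501 genes called for the pool number as a term. With the pool number as a block, 1405 genes differed in mean, 1262 of them shared, 1206 were rhythmic in WT and 416 in KO, and 7 rhythms differed.

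Leaving out each array gave 903 to 1850 genes for the mean difference (514 to 1117 higher, 389 to 740 lower; the 1117 without WT ZT4 pool 2), 602 to 954 for WT rhythm (602 without WT ZT12 pool 2), 77 to 477 for KO rhythm (77 without KO ZT20 pool 2, 206 without KO ZT0 pool 1, 160 without KO ZT8 pool 2, 196 without KO ZT12 pool 2, 146 without KO ZT20 pool 1) and 1 to 11 for rhythm differences (1 without WT ZT0 pool 2 or KO ZT0 pool 1, 2 without WT ZT12 pool 2, KO ZT0 pool 2, KO ZT12 pool 1 or KO ZT16, 3 without WT ZT8, KO ZT8 pool 1 or KO ZT20 pool 1, 11 without KO ZT12 pool 2). The ranges were 0 to 13 at ZT0, where 18 arrays took the count to 2 or fewer and either WT ZT4 pool to 13, 0 to 13 at ZT4 (12 and 13 without a WT ZT4 pool, 0 without a KO ZT4 pool), 0 to 5 at ZT8, where 15 arrays took it to 2 or fewer, 2 to 55 at ZT12 (55 without a WT ZT4 pool, 4 and 2 without WT ZT12 pools 1 and 2, 2 and 37 without KO ZT12 pools 1 and 2), 2 to 23 at ZT16 (23 without a WT ZT4 pool, 4 without WT ZT16 pool 2 or a KO ZT20 pool) and 21 to 366 at ZT20 (21 without WT ZT20 pool 2, 68 and 46 without KO ZT20 pools 1 and 2). They were -2.44 to -1.94 h for the peak shift, 0.856 to 0.982 for the amplitude ratio, 10 to 17 for lists and 1.77 to 3.31 for the odds ratio (1.77 without WT ZT12 pool 1, Fisher's exact test, p = 0.0990). The group-means fit and the single-time contrast cannot be made at ZT8 without its WT array or at ZT16 without its KO array. Over the 76 named results, these fits kept 1445 calls, lost 223 and reversed 0. A reversal was hardly possible, since the fits share most arrays and amplitudes have no sign. On arrays, signal over background takes the place of depth, and the 30th percentile filter left dim probe sets untested.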

Other observations

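The fit without the KO pools at ZT20 was chosen after seeing the data, the other tests in this part before, and the genes named are called members of lists fixed in advance. The camera test asks for a shared direction, and lists not described above are given here. Of 10 tubular injury genes, Fgg, Fgb and Clu (0.28 ± 0.05 log2) were higher and Havcr1 (-0.29 ± 0.07), a marker of proximal tubule damage, was lower (camera adjusted p = 0.163). Proximal tubule markers had 2 of 15 higher, among them the lactate transporter Slc5a12 (0.24 ± 0.04), and 4 lower, among them Slc22a6 (-0.28 ± 0.06) (adjusted p = 0.0716). Thick ascending limb markers had 1 of 7 higher, Cldn10 (0.12 ± 0.04), and 1 lower, Umod (-0.09 ± 0.03) (adjusted p = 0.156). Endothelin and nitric oxide genes had 1 of 8 higher, Ece1 (0.19 ± 0.03), podocyte markers 1 of 6, Ptpro (0.17 ± 0.04), and adipose markers 1 of 7 lower, Lpl (-0.28 ± 0.07). The glucocorticoid list had 1 of 14 lower, Fkbp5 (-0.49 ± 0.08). Immediate early genes (18), heat shock genes (13), urothelium and papilla markers (8), adrenal markers (3), erythroid markers (2) and cold-inducible genes (2) had 0 members called in limma for the mean difference, and 2, 3, 3, 0, 1 and 0 at an unadjusted p under 0.05. Without the KO pools at ZT20, Umod, Lpl, Cldn10 and Ptpro lost their call (adjusted p from 0.0663 to 0.144), and Slc22a6 differed by -0.18 (adjusted p = 0.0295). In that fit Umod (-0.101), Cldn10 (0.116) and Ptpro (0.153) kept about their size, and Lpl (-0.192) shrank.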
